A study of Brachypodium distachyon with 796 samples.

How the data were processed

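RNA was measured in juvenile leaves of 796 independent lines of the grass Brachypodium distachyon, all derived from the inbred genotype Bd21-3. Per the labels, 769 mutant lines descended from seeds treated with 7 mM sodium azide, a chemical mutagen, and 27 control lines from seeds carried through the treatment with 0 mM. Leaves were taken 6 generations later, and each line gave 1 poly(A)-selected library from 3 pooled plants, sequenced as paired reads of 150 bp. The labels placed the lines in 5 batches, each with both groups. Batches 1 to 5 held 175, 176, 180, 186 and 52 mutant lines and 6, 6, 6, 5 and 4 control lines.

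The authors deposited TPM values, a length-corrected relative abundance of transcripts, for 27914 genes in each line. The submitters' processing notes name HISAT2, SAMtools, featureCounts and Subread, without versions. The genome build, the annotation and any filter on genes were not given in the sources used here. TPM values divide the reads of a gene by its length and scale each library to the same total, so the values of each line summed to 1e+06 and a rise in abundant genes lowers all others. Whether the counting used strand, and how it treated reads shared by near-identical genes, was not given in the sources used here, so such genes are uncertain.

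Gene identifiers carried the chromosome and a locus number but no name. None of the identifiers (0 of 27914) matched the reference table used here, which holds 31335 genes of the Bd21 assembly under other identifiers. Genes are therefore named by identifier only, with at most 2 in each direction per comparison. The lists of genes and the known loci fixed before the data were examined could not be looked up, and the list tests were not run. Gene order came from the locus numbers, and no coordinates were used here.

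TPM keeps no absolute depth. The lowest values of a gene were whole multiples of what 1 read was worth in a line, which gave the relative depth of the lines from 1786 genes detected in 3% to 15% of lines. Of 113476 such values, 97.7% lay within 0.1 of a whole number of reads. For these genes 1 read was worth a median of 0.0260 TPM in a line of median depth (interquartile range 0.0178 to 0.0396), so that 10 TPM stood for about 384 reads. Reads are not independent molecules, and such numbers cover counting error only.

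Values were analysed as log2(TPM + 1), which understates the change of genes with low levels. Genes with a mean of at least 1 TPM over all lines (15939) were tested. Mean levels were compared between mutant and control lines in limma 3.58.1 (R 4.3.3; lmFit and eBayes with trend) with batch as covariate. Calls required a Benjamini-Hochberg adjusted p under 0.05, two-sided. Spread between lines was compared by applying the same model to the absolute, leverage-scaled residuals of each gene. The ratio of the standard deviation (SD) in mutant lines to that in control lines was summarised by its median over genes. Batches were compared by limma's moderated F-test with group as covariate. For these tests, control labels were redrawn within batches until 100 splits, the real one included, had been fitted.

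Rare large changes in single lines were counted in 3 ways. An outlying gene lay at least 1 log2 unit and at least 5 robust SDs (from the median absolute deviation, floor 0.1) from the median of the batch. A lost gene had a batch median of at least 10 TPM, a 5th percentile over all lines of at least 25% of its overall median, and at most 5% of the batch median in the line. A gained gene had a 95th percentile of at most 1 TPM over all lines and at least 10 TPM in the line. Counts per line were compared by two-sided permutation tests within batches with 100000 draws, on log2(count + 1) for outlying genes. Lines with runs of at least 3 lost neighbours were compared by Fisher's exact test, two-sided. Neighbours were next to each other among the genes that could be called lost in the batch, so other genes may lie between them. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

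The tests were tried on simulated data with the real group sizes and 15939 genes. For mean levels and spread, the simulated genes were independent of each other, with normal values and no batch effect. Real genes vary together and differ between batches, so recovery and false calls may differ in the real data. The test of mean levels recovered 90% of 100 planted shifts of 0.5 log2 units and 99% of 100 shifts of 1 log2 unit, with 12 false calls. For spread, the planted genes all had the larger SD in mutant lines. The test recovered 0% of 100 genes with a planted SD ratio of 1.5 and 7% of 100 with a ratio of 2, with 0 false calls. A list of genes with larger spread in mutant lines is therefore far from complete. Smaller spread in mutant lines was not simulated, so recovery in that direction is not known. For lost genes, 100% of 200 planted losses were called among 7547 genes, with 0 false calls. Lost genes are called by a fixed threshold, so this checks that the rule was applied. It does not measure how many real losses the rule finds.

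Alternatives fixed before the data were examined covered the pseudocount, the filter on low values, 2 other scalings, batch, depth, hidden factors, thresholds, and each control line left out in turn. Others were added after seeing the data, mostly to leave out control line C14. Named genes followed a rule set before the data were examined. It took the smallest p for mean levels, the SD ratios furthest from 1 in each direction among calls, and the highest batch median among genes lost in 1 line or the 10 genes lost in most lines. It also took the highest TPM among gained genes, the largest SD among genes of at least 10 TPM, and the 5 genes of largest F between batches. Only some of the genes it took are named in the text. Genes named outside this rule are said to be so. Mutations of the lines were not analysed here.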

Results

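The data hold gene expression in leaves of 769 mutant lines and 27 control lines of Brachypodium distachyon, a small grass used as a model for cereals. The series set out to relate sequence changes in mutant lines to expression, and its groups allow lines from azide-treated seeds to be compared with lines from seeds of the same genotype treated with 0 mM azide. The line was the replicate, with 1 library from 3 pooled plants. Libraries held reads for a median of 22191 genes in mutant lines (range 19882 to 24445) and 22080 genes in control lines (range 17699 to 22979). Relative depth, with the median line at 1, ranged from 0.192 to 3.54 in mutant lines and from 0.421 to 1.36 in control lines. A few genes took much of each library: the gene of highest mean level, BdiBd21-3.1G0697600, named after its values were seen, averaged 59257 TPM, and the 10 highest genes of the lines together took a median of 25.6% of TPM (range 13.999% to 37.5%).

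Mean levels of genes did not separate mutant from control lines. None of the 15939 genes passed the adjusted threshold in limma (0 genes, against 310 at an unadjusted p under 0.05), and 49.5% of the estimated differences were above 0. Redrawn labels gave a median of 494 genes at the unadjusted threshold, so the 310 are no excess. The largest estimate was 0.56 log2 units and no gene reached 1 log2 unit (0 genes). The median standard error was 0.08 log2 units, so the 95% interval of a typical gene extended 0.15 log2 units to either side. Of the genes nearest to the threshold, none of which passed, BdiBd21-3.2G0437700 averaged 8.48 ± 2.07 TPM (SD, n = 769) in mutant lines and 7.16 ± 1.89 TPM (SD, n = 27) in control lines. Its difference was 0.20 log2 units (SE 0.05, adjusted p = 1 in limma). BdiBd21-3.2G0067500 averaged 13.4 ± 3.20 TPM (SD, n = 769) against 11.7 ± 3.36 TPM (SD, n = 27). With lower estimates in mutant lines, BdiBd21-3.3G0375500 averaged 2.14 ± 1.09 TPM (SD, n = 769) against 2.71 ± 1.11 TPM (SD, n = 27), a difference of -0.26 log2 units (SE 0.07). BdiBd21-3.3G0137900 averaged 1.55 ± 0.908 TPM against 2.12 ± 1.05 TPM in the same lines. Within batches, limma gave 0 genes in batches 2, 3, 4 and 5 alone and 751 genes in batch 1 alone, of which 734 were higher in mutant lines. Without control line C14, 1 of the 6 control lines of batch 1, that batch also gave 0 genes.

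**Figure D1:**
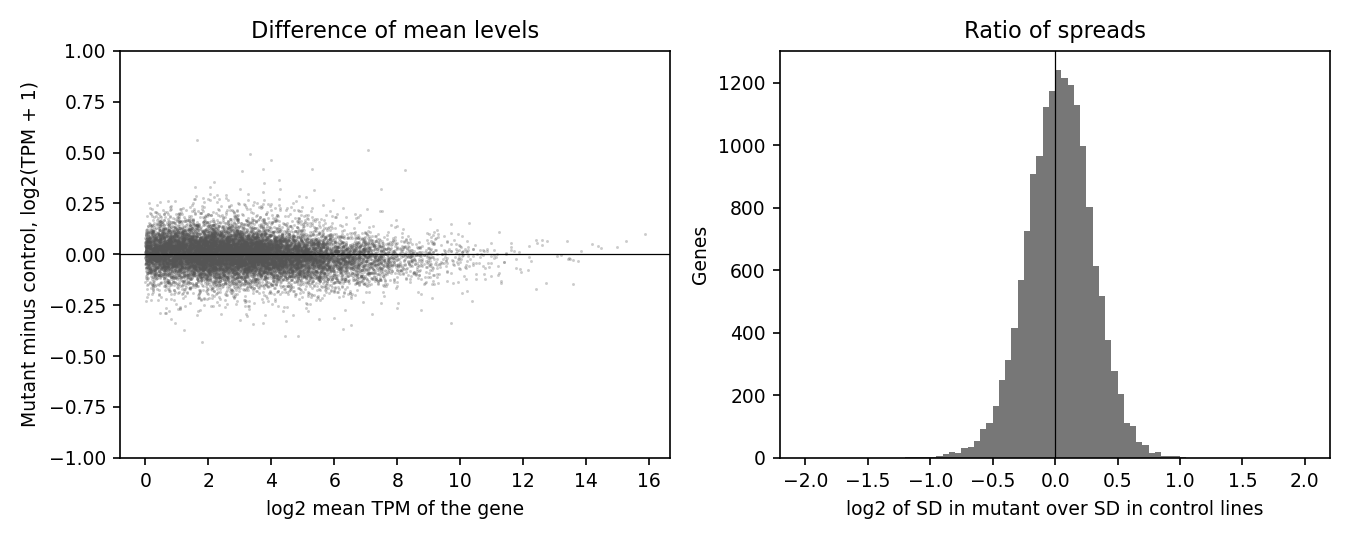
Left, each point is 1 of the 15939 tested genes, with log2 of its mean TPM on the x axis and the mutant minus control difference in log2(TPM + 1) on the y axis. Right, the number of genes by log2 of the ratio of the SD in mutant lines to that in control lines. No difference of means reached 1 log2 unit, and the median SD ratio was 1.03.

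Spread between lines was also close to equal in both groups. The SD of a gene over mutant lines was a median of 1.03 times that over control lines (interquartile range 0.909 to 1.15 over genes), and 56.2% of genes had the larger SD in mutant lines. Redrawn labels gave this median ratio a median of 1.03 and an SD of 0.0585, so the real value lay where labels drawn by chance put it. Spread was not compared within single batches, which held 4 to 6 control lines. After batch and group were removed, the SD of the median gene was 0.40 log2 units. The test of spread called 3 genes in limma, all with the smaller spread in mutant lines, and 1088 genes had an unadjusted p under 0.05. Labels were not redrawn for the unadjusted count. Pooling the variance over 769 mutant and 27 control lines can favour calls in 1 direction, and smaller spread in mutant lines was not simulated. The shared direction of the 3 genes is therefore not read as a result. For BdiBd21-3.2G0345800 the SD was 0.34 log2 units in mutant and 0.76 log2 units in control lines, a ratio of 0.448 (adjusted p = 0.0215 in limma). For BdiBd21-3.4G0386300 the ratio was 0.497 (adjusted p = 0.0443 in limma). The remaining gene, with the smallest adjusted p, had a ratio of 0.566 (adjusted p = 0.0067 in limma). Without control line C14 the count was 0 genes, the ratios of these 3 genes were 0.6408, 0.6167 and 0.6249, and the median ratio over all genes was 1.09. The count of genes depended on the pseudocount, filter and scaling. With 10 principal components as covariates it was 223 genes, and the median ratio was 0.917, below 1. Labels were not redrawn for spread in this setting, so the ratio given by chance is not known. With 10 components and without C14, the count was 0 genes and the median ratio 1.02.

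Large departures of single genes were found in most lines of both groups. A mutant line held a median of 3 outlying genes (interquartile range 1 to 8, n = 769) and a control line a median of 3 (interquartile range 1 to 8, n = 27). None were found in 120 mutant and 3 control lines. In mutant lines there were 7643 such values in 2772 genes, of which 6113 were above and 1530 below the batch median, and with 10 principal components removed 3288 of 4817 were above. A gene with a batch median under 1 TPM cannot fall by 1 unit of log2(TPM + 1), while rises have no such limit. The numbers above and below therefore do not show that rises are more common than falls. The line with most was control line C14, with 615 outlying genes, followed by mutant line M1132, with 376. With 10 principal components removed, C14 had 1393, M1132 had 52 and the highest mutant line, M0537, had 176. With no components removed, the difference of mean log2(count + 1), mutant minus control, was -0.21 (permutation test within batches, p = 0.512), and 0.05 without C14 (permutation test, p = 0.803). Medians of mutant lines in batches 1 to 5 were 2, 5, 3, 3 and 3, and those of control lines 1.5, 6, 3.5, 3 and 5. With 10 principal components removed, the difference was 0.06 (permutation test, p = 0.803).

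**Figure D2:**
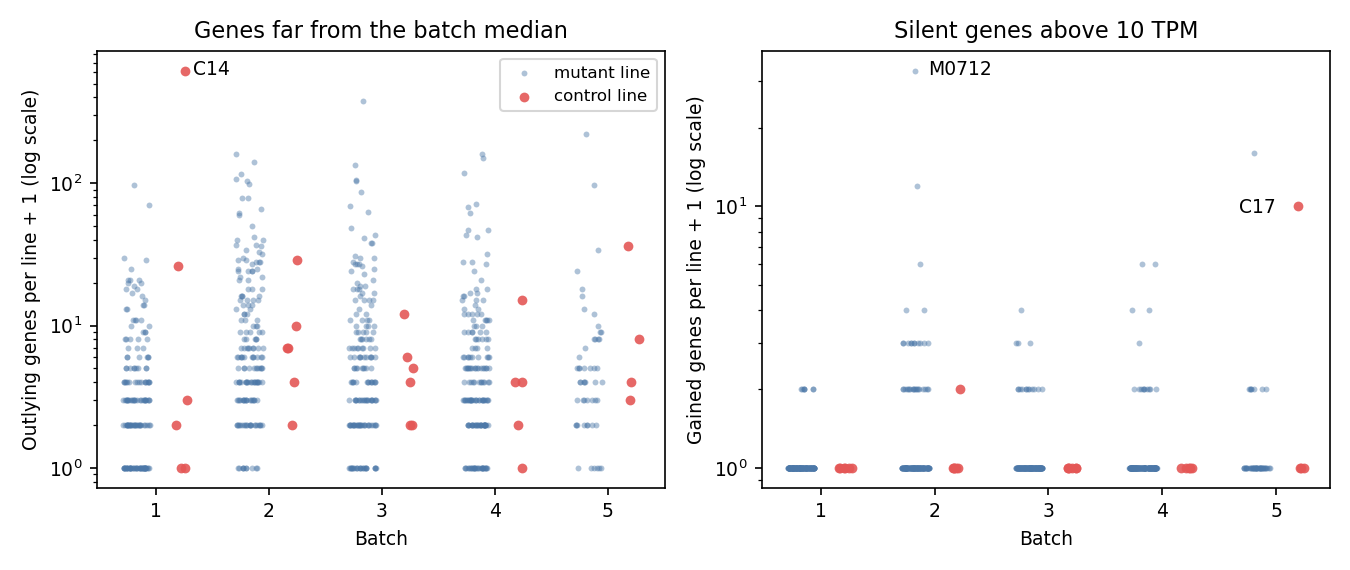
Each point is 1 line, by batch on the x axis, with mutant lines as small points and control lines as large points. The y axes give the number of outlying genes (left) and of gained genes (right) plus 1, on a log scale. Control line C14 had 615 outlying genes, mutant line M0712 had 32 gained genes and control line C17 had 9.

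Near-complete loss of a gene that most lines expressed was rare. It was seen 58 times in 42 of the 769 mutant lines (5.46%, 95% exact binomial interval 3.96% to 7.31%) and involved 42 of 7547 eligible genes. Of these, 34 were lost in a single mutant line and 8 in at least 2. BdiBd21-3.2G0181800 on chromosome 2 had a batch median of 4318 TPM but 14.9 TPM in M0728 and 33.8 TPM in M0535, and the lowest of all other lines had 1186.4 TPM. BdiBd21-3.2G0426200, also on chromosome 2, had 4.36 TPM in M0537 against a batch median of 388 TPM, and the lowest other line had 27.7 TPM. The gene lost in most lines was at 2.31 to 3.73 TPM in 7 lines of batch 4, where its median was 75.6 TPM, but its 5th percentile in that batch was 4.04 TPM, close to the values called lost. In control lines, 15 losses were seen, all of them in C14, and 0 in the other 26 lines, which allows a share of lines of up to 11.5%. Mutant lines had a mean of 0.0754 lost genes and control lines 0.556 (difference -0.48, permutation test within batches, p = 0.0340). Without C14 the means were 0.0754 and 0, and the difference was 0.0754 (permutation test, p = 0.377). Mutant lines averaged 0.0171, 0.108, 0.0778, 0.0968 and 0.0769 lost genes in batches 1 to 5, and control lines averaged 2.5 in batch 1 and 0 in each other batch. The counts depended on the limit. At 10% of the batch median, 286 losses were seen in 163 of 769 mutant lines, and 5 in 3 of the 26 control lines other than C14.

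No line of either group had a run of 3 neighbouring lost genes (0 of 769 mutant and 0 of 27 control lines, Fisher's exact test, p = 1). A count of 0 allows shares of up to 0.390% of mutant and 11.1% of control lines. Neighbours were taken only among the genes that could be called lost, at most 7547 of 27914. The limits therefore do not cover losses of 3 genes in a row that include genes outside this set. Runs of 2 neighbours were found in 1 mutant and 1 control line (Fisher's exact test, p = 0.0667). The mutant line was M0334. In it, a pair of genes chosen after their values were seen, BdiBd21-3.4G0227200 and BdiBd21-3.4G0227300 on chromosome 4, were both listed at 0. Their batch medians were 18.3 and 12.1 TPM, and no other line was below 6.09 and 5.84 TPM. The control line was C14.

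Gained genes were at most 1 TPM in nearly all lines. They were found in 81 of 769 mutant lines (10.5%, 95% exact binomial interval 8.45% to 12.9%) and 2 of 27 control lines. In mutant lines they were 120 of 9477 eligible genes, 93 of them in a single mutant line and 27 in at least 2. BdiBd21-3.4G0326400 on chromosome 4 was at 14.2 to 644 TPM in 13 mutant lines and at most 1.10 TPM in the other 783 lines, where its median was 0.0977 TPM. It was listed at 0 in 69 of these 783 lines, so it was low rather than absent in the rest. BdiBd21-3.5G0311700 on chromosome 5, gained in 5 lines, reached 129 TPM in M0712. Mutant line M0712 alone held 32 gained genes, mutant line M1018 held 15, mutant line M0569 held 11 and control line C17 held 9. Mutant lines had a mean of 0.225 gained genes and control lines 0.370 (difference -0.15, permutation test within batches, p = 0.738). Without C17 the means were 0.225 and 0.0385 (difference 0.19, permutation test, p = 0.289), and without M0712 they were 0.184 and 0.370 (permutation test, p = 0.329). Means of mutant lines in batches 1 to 5 were 0.04, 0.540, 0.117, 0.151 and 0.423, and those of control lines were 0, 0.167, 0, 0 and 2.25.

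Batch accounted for far more of the variation than group. It explained a median of 23.9% of the variance of a gene (interquartile range 13.8% to 36.1%), against 0.0276% for group beyond batch. These shares do not compare sizes of effect. Only 27 of 796 lines were control lines, which keeps the share of group small even where levels differ. Levels differed between batches in 15882 of 15939 genes, and in 6023 genes among the 27 control lines alone. Genes with the largest F were mostly set apart in batches 2 and 3. In batches 1 to 5, BdiBd21-3.3G0226000 averaged 131.7, 1427, 2175, 382 and 81.9 TPM in mutant lines (SD 69.0, 825, 1443, 152 and 56.3). In control lines it averaged 186, 1057, 1639.3, 460 and 67.8 TPM (SD 107, 808, 326, 125 and 31.2). BdiBd21-3.5G0342900, also among the 5 genes of largest F, was lower in batches 2 and 3 than in the others, with 80.4, 35.6, 28.0, 84.2 and 77.9 TPM in mutant lines and 77.2, 37.1, 27.7, 80.0 and 82.9 TPM in control lines. Batches 2 and 4 were furthest apart: 1444 genes differed by at least 1 log2 unit between their mutant lines, of which 117 were higher in batch 4 and the rest lower. Batches 1 and 5 were closest, with 139 such genes. For each pair of batches, the difference in mutant lines correlated across genes with that in control lines, with r from 0.722 to 0.946. Genes are not independent replicates, so no p is given.

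**Figure D3:**
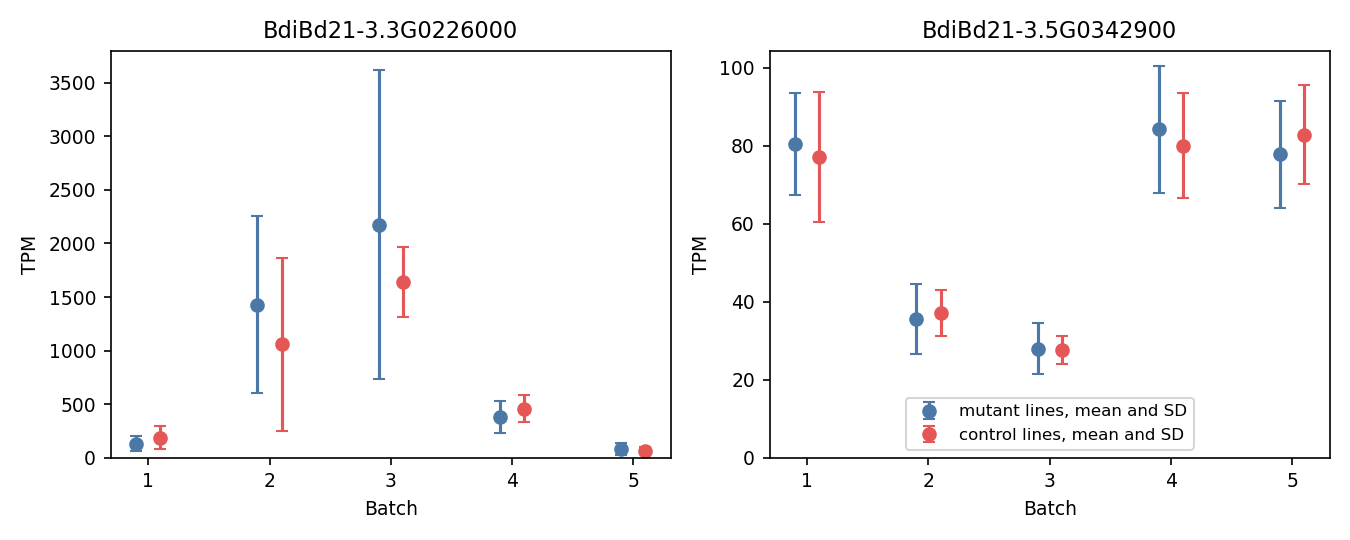
TPM of BdiBd21-3.3G0226000 (left) and BdiBd21-3.5G0342900 (right) by batch. Points are means and bars are SDs over the mutant lines (175, 176, 180, 186 and 52) and control lines (6, 6, 6, 5 and 4) of each batch. In both genes, batches 2 and 3 are set apart from the others in the same direction in mutant and control lines.

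Some genes varied widely between lines of both groups within batches. Among the 6929 genes of at least 10 mean TPM, the SD over mutant lines after batch was removed was a median of 0.40 log2 units. It was largest for BdiBd21-3.5G0066700, at 2.17 log2 units in mutant and 2.52 log2 units in control lines, with 5th and 95th percentiles of 0.596 and 238 TPM over all lines. It was next largest for BdiBd21-3.1G0662000 on chromosome 1, at 2.17 log2 units in mutant and 2.64 log2 units in control lines, with a 95th percentile of 84.7 TPM.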

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

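The tests on line C14 and the genes shared by C17 and M1018 were chosen after their values were seen, as were the splits without C14. Redrawing the labels of all lines was planned, but how the counts of splits would be read was written down only after they were seen. In each batch of 4 to 6 control lines, 5 measures were searched for a line far from the others, and 8 were found in 25 such groups. Chance gives about 5% of groups with normal values, but counts with many values of 0 give more, so the 8 are no measure of excess. For 3 of them all other lines were at 0, where any other value stands apart. In batch 1, C14 had 615 outlying genes against 0 to 25 in the other 5 control lines, 15 lost genes against 0, and 17699 genes above 0 TPM against 21566 to 22218. In batch 2, C37 had 28 outlying genes against 1 to 9, and 1 gained gene against 0. In batch 4, C77 had 14 outlying genes against 0 to 3. In batch 5, C17 had 35 outlying genes against 2 to 7, and 9 gained genes against 0.

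C14 stood apart from all other lines, and not only from the control lines of its batch. After 10 principal components were removed it had 1393 outlying genes, 670 above and 723 below the median. These lay on all 5 chromosomes, from 7.42% of tested genes on chromosome 4 to 9.59% on chromosome 2. Its relative depth of 0.421 does not account for all of this, since the 8 lines of lower depth had at least 19906 genes above 0 TPM, against 17699 in C14. Those lines had at most 94 outlying genes after the components were removed, against 1393 in C14, and at most 220 before, against 615 in C14. A mutant line under a control label is left open, although none of the 769 mutant lines matched C14 in either count. After the components were removed, the highest was M0537 with 176 outlying genes, which had 77 before. Before they were removed, the highest was M1132 with 376, which had 52 after. Plants of another genome cannot be told apart from another state of the tissue. In C14, 40 genes of a median of at least 5 TPM were listed at 0, against at most 7 in any other line. But C14 had 0 gained genes, and no sequence was used here. The quality of the RNA and of the library was not examined, so a part for either is not excluded. In genes of at least 100 mean TPM, the SD of C14 over genes was 0.775 log2 units after the components were removed. The highest other line had 0.552 log2 units.

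C17 and mutant line M1018, both in batch 5, shared 20 outlying genes after 10 components were removed, of 53 and 70, where independent lists would share 0.233. They also shared 5 gained genes, of 9 and 15.

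Redrawing the control labels within batches did not exclude chance for the counts of genes with a different mean level or spread, or for the median SD ratio. The real labels gave 0 genes with a different mean level, which all 100 splits must reach, with 559 in the highest other split. At an unadjusted p under 0.05 they gave 310 genes, and 71 of 100 splits gave at least as many (highest other 5144). They gave 3 genes with a different spread, and 23 of 100 splits, the real one included, gave at least as many, with 579 in the highest other. The median of the other splits was 0 for both adjusted counts, so the highest values come from few splits. Structure shared between lines may produce such splits, which was not tested. The median SD ratio of 1.03 was reached by 51 of 100 splits (highest other 1.21), and the ratio of 1.09 without C14 by 16 of 100 (highest other 1.17).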

How the results depend on the processing

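Settings that leave out C14 together with another change, C17 or M0712, that use principal components of the batch residuals, and the F-test were chosen after seeing the data. So were those that leave out single lines from the SD ratio, outlying, lost and gained genes. The cause of a change was not tested unless stated. The count of genes with a different mean level was 0 in 41 settings, with each of the 27 control lines left out (0 to 0) among them. It was 22 with no filter on low values, 751 in batch 1 alone (0 without C14), 208 with 10 principal components as covariates and 13 with these and without C14. For the 208, chance was not excluded, since 84 of 100 splits gave as many (highest other 8272), and components of the batch residuals gave 0. The count with a different spread, 3, was 50 with a pseudocount of 0.1, 378 with no filter, 5 at a mean of at least 5 TPM, 28 with median-of-ratios scaling, 17 with quantile normalisation and 0 with no batch covariate. It was 223 with 10 components and 219 with those of the batch residuals, both 0 without C14, and 250 with the F-test. It ranged from 0 (without C14) to 17 (without C64) when control lines were left out. The median SD ratio fell from 1.03 to 0.917 with 10 components of either kind (0.916891 and 0.916601), and was 1.02 without C14 as well. It ranged from 1.02 to 1.09 with control lines left out. Batch differences covered 24438 genes with no filter, where more genes are tested, and 6023 and 6434 genes among control lines with and without C14, where fewer lines are. Signs turned for outlying genes (0.0553 with 10 components, 0.388 with these and without C14, 0.0475 without C14 alone), lost genes (0.0754 without C14, 0.180 without it at 10% of the batch median) and gained genes (0.0323 at 5 TPM, 0.187 without C17, but -0.187 without M0712). None of these was past its threshold. Runs of 2 lost genes were found in 1 mutant line and 1 control line, C14. The list tests were not run, since no gene had a description. No paired analysis was possible because the groups share no replicate labels. In the main setting losses were sought only in genes of at least 10 TPM, about 384 reads in a line of median depth. At a batch median of at least 5 TPM, 116 losses were seen in 78 mutant lines and 58 in 1 control line, C14. Losses of weaker genes stay unseen.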

Other observations

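All tests of neighbouring genes and of the gene BdiBd21-3.4G0326400 were chosen after these patterns had been seen.

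A small share of genes next to each other on a chromosome varied together between mutant lines, while the median correlation of adjacent pairs was 0.0220. After batch and 10 principal components were removed, 137 of 15934 adjacent pairs of tested genes correlated above 0.5 (0.860%), against 0.0388% of 46440 random pairs on different chromosomes (95% exact binomial interval 0.0230% to 0.0613%). Of pairs 2 steps apart, 0.251% correlated above 0.5 (95% exact binomial interval 0.179% to 0.342%), and of pairs 3 steps apart 0.151% (0.0966% to 0.224%). Both genes of such a pair can share reads with genes between them, so reads shared between adjacent genes are not excluded. The intervals take pairs as independent, although pairs share genes. At 10 steps the share was 0.0629% (0.0302% to 0.116%), an interval that overlaps that of different chromosomes, and at 50 steps it was 0.0191%. Reads shared between near-identical copies cannot be told apart from shared regulation, for the 137 adjacent pairs or the others, because no sequence was used here. A shared control of neighbouring genes may contribute, as a hypothesis.

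BdiBd21-3.4G0326400 was gained in 13 mutant lines and 0 control lines. A large change of expression shared by the segment is argued against, since 0 of the 13 lines had an outlying gene among its 10 nearest tested genes, which are those of at least 1 mean TPM. Reads from a neighbouring gene were not tested. Batch alone is argued against as well, since the 13 lines lay in 4 batches, although 9 of them were in batch 2 (Fisher's exact test for batch 2 against the others, p = 0.000434). A part for batch is therefore not excluded. Mutant lines of batches 1, 2 and 3 carried largely successive numbers, so batch cannot be told apart from the order of the lines. Whether azide treatment is needed cannot be told, since the share of control lines would give 0.441 lines with the gene gained. Mutation of the gene or of a regulator, and silencing that is unstable between lines, remain candidate explanations that were not tested.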
